A study of Camelus bactrianus with 10 samples.

How the data were processed

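Small RNA was measured by sequencing in exosomes from the blood plasma of 10 Bactrian camels, 5 labelled thin and 5 labelled normal, with 1 column of values per camel. The labels' protocol speaks of 9 libraries, while the labels and the table give 10, and the difference was not settled here; every n = 5 rests on the labels and the table. Per the labels' protocols, exosomes were pelleted by ultracentrifugation of plasma, RNA was extracted with the mirVana kit, libraries were made with the TruSeq small RNA kit, and sequencing was done on an Illumina HiSeq instrument. Per the same protocols, reads were filtered with the program ACGT101-miR, which removed adapter dimers, junk, low complexity reads, common RNA families and repeats. The mapping reference, the miRBase version, the genome build and the minimum count were not given in the sources used here. A filter of this kind removes reads that match small nuclear RNA, so that a miRNA sharing sequence with such an RNA can lose or keep reads depending on that step.

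The deposited values were a signal that the authors' column headers called normalized counts, with 1 column per camel and no column of the authors' own comparisons. How the factor of each library was made was not given in the sources used here. The table listed 2581 small RNAs, of which 969 carried a miRNA name and 1612 were predicted. Names were those of the table: they gave the species of the matched entry, and letters for bases gained or lost at the left or right end. A further 2 lines of the table were empty and were not used here. Low values in a library were nearly all multiples of 1 step (98.8% to 99.9% of values up to 200 steps, within a tolerance of 0.02 of a step). Of 8344 positive values, 99.964% were at least 5 steps, so a value of 0 stood for fewer than about 5 reads and not for absence. Dividing each total by its step gave an estimate of the reads in the table, from 505266 to 4474902 per library. The step test applied to the whole table did not recover whole reads for nearly all small RNAs, so no count test was run, and the estimated reads served only to describe depth and for 1 alternative. No genome was used here, and no coordinates are given.

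The design fixed before the data were examined assumed raw counts and named limma on log2 values as the test for normalized ones. That second test was used. Values were taken as log2(value + 1) for the 468 small RNAs at 10 or more in at least 5 libraries, and limma 3.58.1 with a mean trend was fitted in R 4.3.3 with group as the only term. Fold changes are thin over normal on that log2 scale, which understates changes of low small RNAs, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 468 tested small RNAs held 454 distinct sequences under 419 mature names. Rows that differ by 1 or 2 end bases are isomiRs of 1 miRNA and are not independent. Near-identical family members, such as those of let-7 and miR-320, can share reads, and their separate values are uncertain to that extent.

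The same test was tried on simulated data with the means and spreads of the 468 small RNAs over 20 runs. It called 22.3% of 2-fold changes, 49.7% of 4-fold changes and 78.0% of 8-fold changes, with 1.35 false calls per run. Most 2-fold changes were therefore missed in this simulation. Its spreads came from the data and already held counting noise, which was then added again, so these shares may be too low. It also planted more changes than the real comparison called, which eases the adjusted threshold, so they may instead be too high. Simulated small RNAs varied independently of each other, unlike real ones, so the false calls may differ from those in real data.

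There were 14 miRNA lists, fixed from general knowledge before the values were seen: red blood cell, platelet, leukocyte, liver, muscle, adipose and lipid, let-7, miR-17 clusters, DLK1-DIO3 locus, epithelial, neuronal, stromal, and those raised or lowered in hepatocellular carcinoma. Lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, all in limma. Members were also counted after adjustment over the list alone. The miRNAs named were chosen by a fixed rule: all called small RNAs with a mean of at least 10 normalized counts, up to 10 in each direction; the 10 with the next smallest p, given as values; the 10 most abundant; and the 2 most abundant tested members of each list with its called members. Names outside that rule were chosen after their values were seen.

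Single values per library were compared by a two-sided exact permutation test over all 252 splits of the 10 libraries, for which the smallest possible p is 0.00794. This covered body weight, 18 measures of library composition, and the log2 ratio of the 5p to the 3p arm in 60 hairpins with its median over hairpins. Correlations used deviations from group means and 100000 permutations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

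Alternatives covered the scaling between libraries, the filter on low values, the pseudocount, the threshold, limma without trend, sample quality weights, merging of rows, the replicate number as a block, and leaving out each library in turn. Upper quartile factors were taken over all 2581 small RNAs, of which only 656 to 1078 were above 0 in a library. In the shallowest libraries that quartile lay near the floor of 5 reads, so these factors could follow depth. After the data were seen, further fits were added with the 3 deepest libraries as a covariate or left out, without normal 4 and normal 5, with 1 row per sequence, without substitution rows, with a common floor, with median ratio rescaling of the calls, with trimmed mean and upper quartile rescaling of the list tests, with an estimated correlation without normal 4 and normal 5, and with limma-voom on the estimated reads. Predicted miRNAs were tested with the rest and were named only where the rule named them. Sets of predicted target genes were not analysed here.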

Results

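Small RNA was sequenced from plasma exosomes, the small vesicles that cells release into blood, of 5 thin and 5 normal Bactrian camels. The series' title connects such exosomes with hepatocellular carcinoma, the main cancer of liver cells. Its tumour experiments and protein data were not analysed here. The labels name 5 camels per group, so the replicates were different animals. Thin camels weighed 412 ± 7.74 kg and normal camels 479 ± 17.1 kg (SD, n = 5 each). The difference was 66.8 kg, or 13.9% of the normal weight, and the groups did not overlap (two-sided exact permutation p = 0.00794, the smallest possible for 5 against 5). As the camels were grouped as thin and normal, this describes the grouping and is not a finding.

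The libraries summed to between 532999 and 757352 normalized counts. The reads estimated from the steps of the values were 1036351, 787403, 1600137, 4312774 and 4474902 in normal 1 to 5. In thin 1 to 5 they were 842447, 505266, 907094, 2938274 and 778055. Normal 4, normal 5 and thin 4 were thus the 3 deepest libraries. The most abundant small RNAs were miR-451a, a miRNA of red blood cells, at 87583 ± 31317 normalized counts in normal and 46257 ± 16185 in thin camels, and miR-21-5p. They were followed by let-7g-5p, miR-486, miR-122-5p, the main miRNA of hepatocytes, and miR-191-5p, with means over all libraries of 31965, 31372, 29286 and 28217 normalized counts. The 10 small RNAs with the highest mean over all libraries made up 44.6% to 53.8% of the total of each library.

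Libraries 4 and 5 of the normal group stood apart from the other 8. The first principal component held 40.2% of the variance and separated the 3 deepest libraries from the rest. The second held 14.7%. Small RNAs named after a miRNA cluster on chromosome 19 that is known from primates alone made up 0.485% of normal 4 and 0.444% of normal 5, at most 0.0103% of any other library, and were listed at 0 in 4 libraries. Of the 54 entries of this cluster, 2 were among the tested small RNAs. This does not show that the other tested small RNAs were unaffected in these libraries. The median Spearman correlation between libraries was 0.777 within normal, 0.868 within thin and 0.843 between the groups, so libraries of the normal group were no closer to each other than to those of thin camels.

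**Figure D1:**
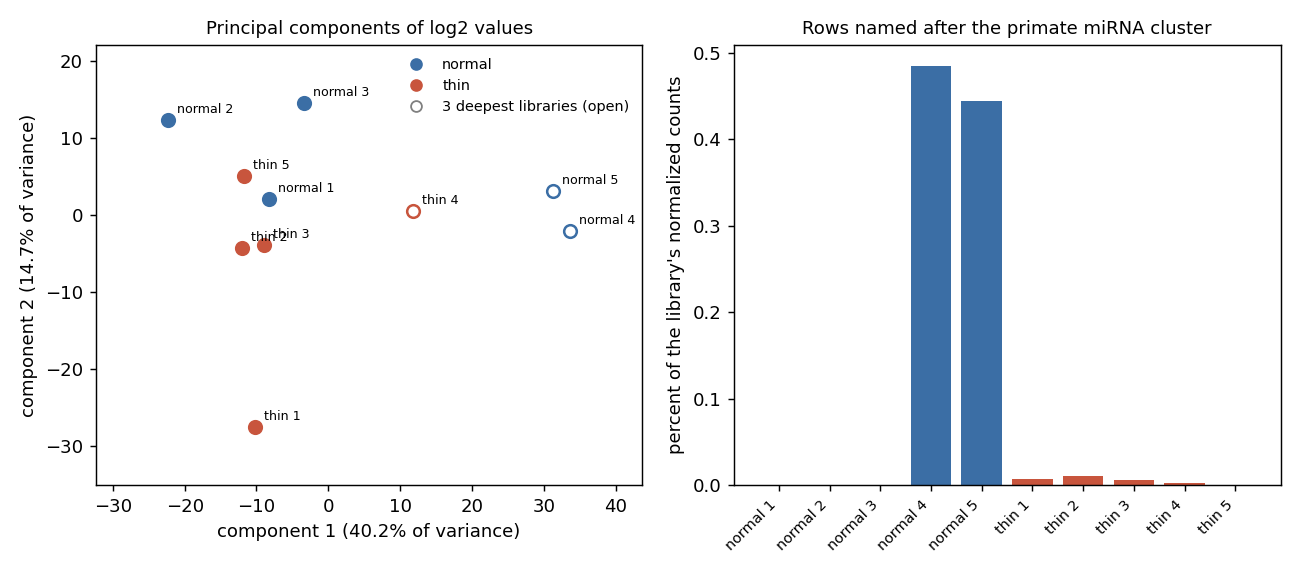
The left panel plots the first and second principal components of the log2 values of the 468 tested small RNAs, 1 point per library, with open points for the 3 deepest libraries. The right panel gives, as bars, the percent of each library's normalized counts in entries of the primate miRNA cluster, which was 0.485% in normal 4, 0.444% in normal 5 and at most 0.0103% elsewhere.

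The first comparison asked which small RNAs of plasma exosomes differed in level between thin and normal camels. Exosomes of thin camels held more miR-335-5p, more of an entry named miR-320c, more miR-1246 and miR-21-5p, and less miR-486, miR-106b-3p and a predicted small RNA. MiR-21-5p, a miRNA raised in many tumours, averaged 37663 ± 5407 normalized counts in normal and 83192 ± 17692 in thin camels (SD, n = 5 each), a log2 fold change of 1.13 ± 0.19 (SE). MiR-486, a miRNA of the red blood cell lineage, averaged 45680 ± 12220 in normal and 17064 ± 4217 in thin camels, a log2 fold change of -1.41 ± 0.24. With limma, 9 of 468 tested small RNAs passed an adjusted p of 0.05, of which 6 were higher and 3 lower in thin camels, and they carried 7 mature names.

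MiR-1246, whose sequence is also found in U2 small nuclear RNA, was represented by 3 isomiRs, all higher in thin camels. The isomiR AAATGGATTTTTGGAGCAGGG (bta-miR-1246_L+1R+1) rose from 121 ± 20.3 to 890 ± 365 normalized counts, a log2 fold change of 2.77 ± 0.34 (limma adjusted p = 0.00102), the smallest p of all tested. The isomiR AAATGGATTTTTGGAGCAGGGA (hsa-miR-1246_L+1R+2) rose by 2.46 ± 0.38 (adjusted p = 0.00672) and ATGGATTTTTGGAGCAGGGA (hsa-miR-1246_L-1R+2) by 2.49 ± 0.46 (adjusted p = 0.0118) on the log2 scale. The entry named miR-320c (AAAAGCTGGGTTGAGAGGG, hsa-miR-320c_R-1) rose from 24.6 ± 16.4 to 230 ± 142, a log2 fold change of 3.27 ± 0.57 (adjusted p = 0.00735). It has lost 1 base at the right end, so its origin among the near-identical members of the miR-320 family is uncertain. MiR-320c stands here for that name in the table. An entry of miR-320c with the substitution G9T, counted from 1 at the 5' end of the read, held 19.5 and 23.5 in normal 4 and normal 5, more than the 7.1 and 13.1 of the tested entry there, and with all entries of miR-320c summed the log2 fold change was 2.62 (adjusted p = 0.00830). MiR-335-5p (TCAAGAGCAATAACGAAAAAT, hsa-miR-335-5p_R-2), encoded within the imprinted MEST gene, had the largest log2 fold change of the called small RNAs, 3.85 ± 0.79 (adjusted p = 0.0238). It was 143 ± 53.3 in normal camels, 16935 in thin 1 and between 313 and 1878 in the other 4 thin camels, and without thin 1 its log2 fold change was 3.07 (adjusted p = 0.0161).

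The adjusted p of miR-21-5p (hsa-miR-21-5p) was 0.00735, as was that of miR-486 (TCCTGTACTGAGCTGCCCCGAGT, bta-miR-486_R+1). MiR-106b-3p (CCGCACTGTGGGTACTTGCT, hsa-miR-106b-3p_R-2), from an intron of the replication gene MCM7, averaged 1975 ± 328 in normal and 999 ± 191 in thin camels, a log2 fold change of -0.99 ± 0.21 (adjusted p = 0.0294). The predicted small RNA PC-3p-1992_4114 (TGAATGGCACCTTATGAGTAGA) averaged 419 ± 143 and 154 ± 38.7, a log2 fold change of -1.41 ± 0.31 (adjusted p = 0.0294). In all 9, every thin library lay on 1 side of every normal library. Of the 468 tested, 17 or 3.63% were separated in this way, against 0.794% by chance. At an unadjusted p under 0.05 there were 55, of which 27 were higher and 28 lower, and the median log2 fold change of all tested was -0.01.

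**Figure D2:**
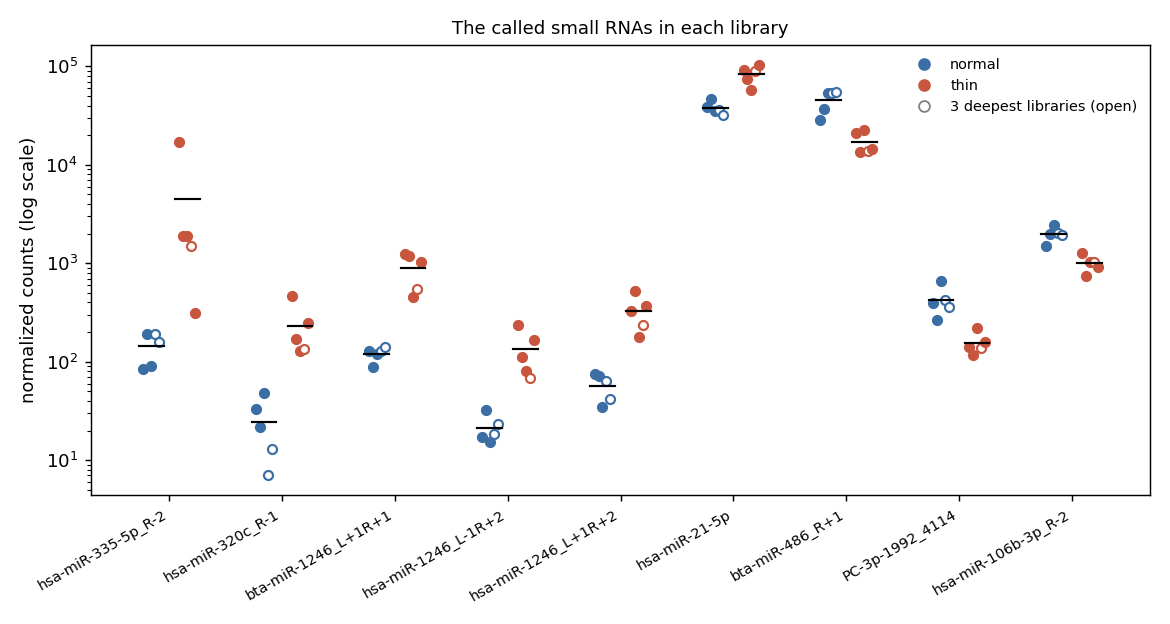
Each point is 1 library's normalized counts on a log axis for the 9 called small RNAs, in normal (blue, left) and thin camels (red, right), with the group mean as a line and open points for the 3 deepest libraries. The points of the groups do not overlap for any of the 9, and thin 1 lies at 16935 for miR-335-5p.

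Without normal 4 and normal 5, which carried the primate cluster entries, 3 calls were left: miR-320c with a log2 fold change of 2.60 (adjusted p = 0.0462), bta-miR-1246_L+1R+1 with 2.88 (0.00656) and hsa-miR-1246_L+1R+2 with 2.41 (0.0445). In that fit of 3 normal and 5 thin libraries the log2 fold changes were 1.04 for miR-21-5p (adjusted p = 0.0904), -1.21 for miR-486 (0.0904), 4.10 for miR-335-5p (0.0753), 2.51 for hsa-miR-1246_L-1R+2 (0.0688), -0.97 for miR-106b-3p (0.177) and -1.44 for PC-3p-1992_4114 (0.164). With each library left out in turn, miR-21-5p, miR-486, miR-320c and the 3 miR-1246 isomiRs passed in all 10 fits. MiR-21-5p and miR-486 missed the threshold with limma without trend (adjusted p = 0.0786 and 0.0733) and after upper quartile rescaling (adjusted p = 0.400 for both), where their log2 fold changes were 1.22 and -1.31. The upper quartile lay near the floor of 5 reads in the shallowest libraries, so losses after that rescaling do not separate scaling from depth. MiR-335-5p missed the threshold without normal 1, 3 or 5 or thin 2, 3 or 4 (adjusted p up to 0.0827), miR-106b-3p without any library but normal 1 or thin 1 (up to 0.0981), and PC-3p-1992_4114 without any but normal 2, thin 1 or thin 3 (up to 0.0969). MiR-335-5p also missed it with limma without trend (adjusted p = 0.0786). MiR-106b-3p and PC-3p-1992_4114 also missed it after trimmed mean rescaling (0.124 and 0.105), after upper quartile rescaling (0.686 and 0.632) and with no filter (0.308 and 0.476). Higher and lower calls numbered 6 and 1 after trimmed mean rescaling, 5 and 0 after upper quartile rescaling, and 6 and 2 with equal library totals. They numbered 6 and 8 without thin 1, 7 and 7 with sample quality weights, and 5 and 6 where 10 or more in all libraries was asked for.

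The 10 small RNAs with the next smallest p are given as values only. MiR-144-3p (log2 fold change -1.09, limma adjusted p = 0.0558), miR-25-3p (-0.84, 0.0616), miR-185-5p (-0.82, 0.084), miR-144-5p (-1.10, 0.135) and miR-451a (-0.92, 0.157) had lower means in thin camels. MiR-142-3p (1.12, 0.135) and miR-223-3p (0.96, 0.157), both of blood cells, miR-19b-3p (0.94, 0.135), miR-22-5p (1.49, 0.153) and miR-221-3p (0.79, 0.157) had higher means. Of the other abundant miRNAs, let-7g-5p (-0.30), let-7f-5p (-0.44), miR-30e-5p (-0.27), miR-26a-5p (-0.12), miR-191-5p (-0.09), miR-122-5p (-0.66) and miR-92a-3p (-0.58) did not pass the test, with adjusted p between 0.258 and 0.926. The log2 fold change of miR-26a-5p turned to 0.18 without normal 4 and normal 5, to 0.042 without normal 5 alone and to 0.0039 without thin 2. Without thin 1, miR-144-3p, miR-25-3p, miR-185-5p and miR-144-5p passed (adjusted p up to 0.0484), as did miR-144-3p and miR-22-5p without normal 1 (0.0226 for both).

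The second comparison asked whether miRNAs of a cell type, tissue or process moved together. All 8 tested members of the red blood cell list had lower mean log2 values in thin camels, with a median log2 fold change of -1.01, and the list passed camera's test (adjusted p = 2.81e-06). The adjusted p was 0.265 with an estimated correlation and 0.0341 with fry. Over all small RNAs only miR-486 fell, and adjusted over the list alone 5 members fell, namely miR-486, miR-144-3p, miR-144-5p, miR-451a and miR-92a-3p. Of the let-7 list, a family that restrains growth and whose members share most of their sequence, 10 of 11 had lower mean log2 values, with a median of -0.43 (camera adjusted p = 0.00376), and no member passed alone or over the list alone. Its median was -0.27 without thin 3 (adjusted p = 0.0480). With all libraries its adjusted p was 0.536 with an estimated correlation, 0.126 with fry and 0.122 after upper quartile rescaling. Without normal 4 and normal 5 the medians were -1.04 for red blood cell (adjusted p = 0.000181) and -0.34 for let-7 (0.0329), and the adjusted p was 0.208 and 0.480 with an estimated correlation. As many as 2 lists were called in 68 of 100 splits of the 10 libraries, the real one included, so the number of lists called was not beyond what other groupings of these libraries gave.

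The lists of hepatocellular carcinoma did not pass. In the list raised in that tumour, 8 of 12 members had higher mean log2 values, with a median of 0.33 (camera adjusted p = 0.09997). MiR-21-5p was the only member past the threshold over all small RNAs, and miR-21-5p and miR-221-3p passed adjusted over the list alone. MiR-10b-5p of this list had a log2 fold change of -0.42. In the list lowered in that tumour, 12 of 19 members also had higher mean log2 values, with a median of 0.34 (adjusted p = 0.121), among them miR-223-3p (0.96), while miR-26a-5p and miR-122-5p had -0.12 and -0.66. Without normal 4 and normal 5 both lists passed with higher values in thin camels, at medians of 0.69 (adjusted p = 0.00464) and 0.43 (0.00331), but not with an estimated correlation (adjusted p = 0.208 for both). They also passed without normal 4 alone (adjusted p = 0.0256 for both) and without normal 5 alone (0.0283 for both).

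Liver miRNAs were lower on average without passing: all 5 members had lower mean log2 values, with a median of -0.56 (camera adjusted p = 0.321), among them miR-122-5p (-0.66 ± 0.59, SE) and miR-192-5p (-0.87 ± 0.55). Without thin 4 these were -0.34 and -0.56, and the liver median turned to 0.08. MiR-122-5p was -0.31 without normal 1 and -1.02 without normal 2. Without the 3 deepest libraries miR-122-5p and the liver median were both -0.17. In the epithelial list 7 of 8 members had higher mean log2 values, with a median of 0.64 (adjusted p = 0.09997), among them miR-200a-3p (1.88 ± 1.05) and miR-200b-3p (1.67 ± 0.97). Without thin 1 these were 0.91 and 0.69, and the list median was 0.56. The median was 0.24 without normal 3, and the list passed without normal 2, normal 4 or thin 4 (adjusted p = 0.0356, 0.0313 and 0.0144) and after upper quartile rescaling (0.0372). It also passed without normal 4 and normal 5, at a median of 1.06 (adjusted p = 0.0195), as did adipose and lipid, at 0.52 (0.0154). With an estimated correlation neither passed in that fit (adjusted p = 0.480 and 0.208). Without the 3 deepest libraries the medians were 1.51 for epithelial (camera adjusted p = 0.00151) and 0.39 for adipose and lipid (0.0301). With all libraries, adipose and lipid had a median of 0.08 (adjusted p = 0.321), with miR-26b-5p at 0.08 and miR-103a-3p at -0.03. The median was -0.03 without thin 1 or thin 4 and 0.27 without normal 5. Muscle had 0.63 (0.363), with miR-1-3p, the miRNA of heart and skeletal muscle, at 0.94 and miR-499a-5p at -0.18. Without thin 2 these were 0.41 and 0.04, and the muscle median was 0.21.

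The remaining lists each had an adjusted p of 0.828. Platelet members had a median of -0.01, with miR-191-5p at -0.09 and miR-126-3p at -0.01. Leukocyte members had 0.10, with miR-150-5p, a lymphocyte miRNA, at 0.11 and miR-142-5p (cgr-miR-142-5p_R-1) at 0.01. Of these members 13 had higher and 8 lower mean log2 values. The lowest, a G9T entry of miR-142-5p (hsa-miR-142-5p_L+2R-3_1ss9GT), had -5.28 (limma adjusted p = 0.164). It averaged 1294 ± 1804 normalized counts in normal and 15.1 ± 26.4 in thin camels, and the list was not tested without it. The miR-17 clusters had -0.05, and adjusted over the list alone miR-25-3p fell and miR-19b-3p rose. Neuronal members had -0.04, with miR-7-5p at -0.04, and stromal members -0.06, with miR-199a-5p at 0.28 and miR-10b-5p at -0.42. Only 2 members of the DLK1-DIO3 locus, an imprinted miRNA cluster, were tested, miR-127-3p at -0.62 and miR-381-3p at -0.30, so the list had no test. Without the 3 deepest libraries these turned to 0.59 and 0.71, and without normal 4 and normal 5 to 0.57 and 0.59. MiR-381-3p also turned to 0.18 without normal 4 alone and to 0.54 without thin 5. The medians of these remaining lists, and the values of miR-191-5p, miR-126-3p, miR-150-5p, cgr-miR-142-5p_R-1, miR-7-5p, miR-26b-5p and miR-103a-3p, changed sign with at least 1 single library left out. MiR-199a-5p was 0.00 without thin 4, and miR-10b-5p was -0.84 without normal 3 and -0.24 without normal 5.

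The third comparison concerned the makeup of the libraries. Red blood cell miRNAs made up 25.2 ± 5.69% of normal and 14.7 ± 3.32% of thin libraries (SD, n = 5 each; exact permutation p = 0.0159, adjusted p = 0.107 over 18 measures). The list raised in hepatocellular carcinoma made up 6.43 ± 1.02% and 14.8 ± 2.61% (exact p = 0.00794, adjusted 0.107), most of which was miR-21-5p with 5.35 ± 1.01% and 13.3 ± 2.61%. Let-7 made up 14.1 ± 0.92% and 12.3 ± 0.92% (exact p = 0.0238, adjusted 0.107), and liver miRNAs 6.40 ± 4.22% and 4.66 ± 3.43% (exact p = 0.516). Predicted small RNAs made up 2.98 ± 3.49% and 3.03 ± 1.86% (exact p = 0.960). Libraries of normal camels held 922 ± 137 small RNAs and those of thin camels 747 ± 86.1 (exact p = 0.0397, adjusted 0.122), but at a common floor of 5 reads of the shallowest library the numbers were 733 ± 112 and 673 ± 107 (exact p = 0.421). None of the 18 measures passed after adjustment, and with a smallest possible p of 0.00794 at least 3 would have had to pass together. Within the 3 normal and 4 thin libraries outside the 3 deepest, red blood cell miRNAs made up 26.2% and 15.6% and the list raised in hepatocellular carcinoma 6.76% and 14.7% (exact p = 0.0571 for both). Adipose and lipid made up 3.55% and 5.11% there (exact p = 0.0286), the mean share of let-7 was lower in thin camels (exact p = 0.0571), and the adjusted p of all 4 was 0.257.

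**Figure D3:**
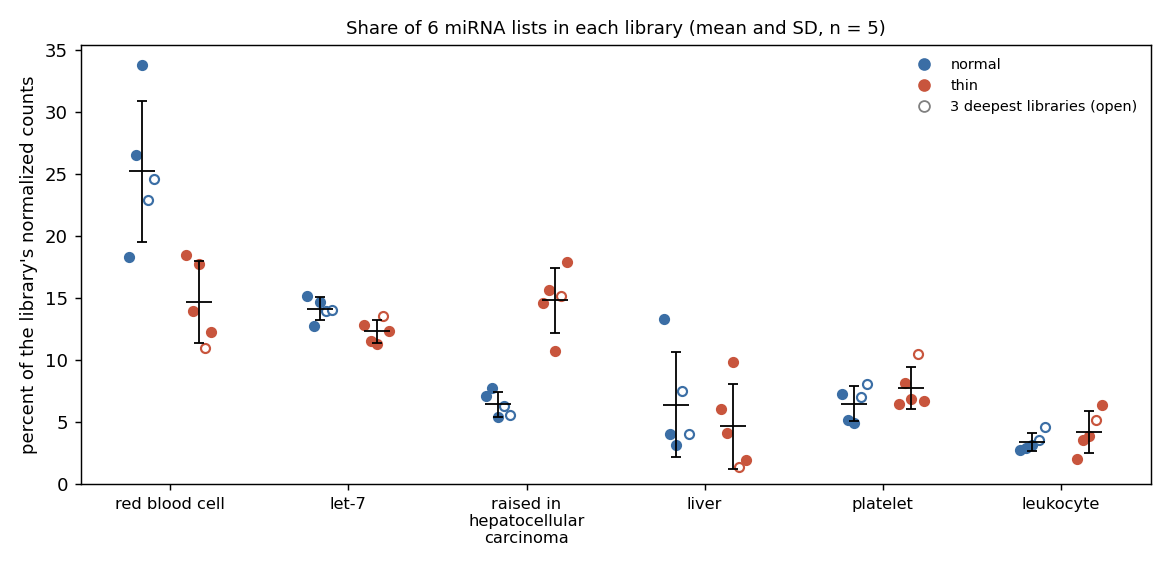
Each point is the percent of 1 library's normalized counts in a miRNA list, for normal (blue, left) and thin camels (red, right), with the mean and SD in black and open points for the 3 deepest libraries. Red blood cell miRNAs averaged 25.2% in normal and 14.7% in thin libraries, and those raised in hepatocellular carcinoma 6.43% and 14.8%.

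The last comparison asked whether the 5p and 3p arms of a hairpin shifted against each other, a ratio that does not depend on the scaling between libraries. The log2 ratio of the 5p to the 3p arm of miR-106b was -0.19 ± 0.17 in normal and 0.47 ± 0.15 in thin camels (SD, n = 5 each), that of miR-142 was 3.81 ± 0.30 and 2.57 ± 0.53, and that of miR-5112 was 0.02 ± 0.42 and -0.76 ± 0.16. In each of these 3 hairpins the groups did not overlap (exact permutation p = 0.00794, adjusted 0.161 over 61 tests). The 5p arm of miR-142 included a G9T entry at 2441 and 3927 normalized counts in normal 4 and normal 5, with a mean of 15.1 in thin camels. That entry raised the ratio of miR-142 in normal 4 and normal 5, and the ratio was not tested without it. None of the 60 hairpins passed after adjustment, and 9 had an exact p under 0.05. At the smallest possible p at least 10 hairpins would have had to pass together, and the median over hairpins did not differ (exact p = 0.262).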

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

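The tests of depth class, of ratios to miR-451a, of the share of miR-21, of the primate cluster and of base substitutions were chosen only after the results were seen; the counts of splits were set earlier.

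Dixon's test, with a critical value of 0.71 for 5 values, singled out 17 of 120 groups of 5 libraries. Chance would give about 6 if the values were independent and normally distributed. The values were not logged, all 17 were the highest of their group, and some groups shared miRNAs. The excess over 6 is thus no evidence of unusual libraries. Thin 1 accounted for 6 of the 17 and normal 2 for 4. In thin 1, miR-335-5p stood at 16935 normalized counts (313 to 1878 in the other thin camels), miR-185-5p at 2865 (2074 to 2185) and miR-126-3p, an endothelial and platelet miRNA, at 13557 (4645 to 7193). MiR-200b-3p, a miRNA of epithelial cells, stood at 5140 in thin 1 (120 to 281) and at 532 in normal 2 (47.3 to 90.9 in the other normal camels). Its cluster partner miR-200a-3p stood at 3298 in thin 1 (88.7 to 158) and at 535 in normal 2 (28.9 to 36.7). The epithelial list as a whole made up 1.39% of thin 1 (0.0875% to 0.234%) and 0.330% of normal 2 (0.0305% to 0.103%), and predicted small RNAs made up 9.07% of normal 2 (0.637% to 2.42%). Among single values elsewhere, miR-22-5p stood at 182 in normal 1 (34.6 to 63.3), let-7g-5p at 41926 in normal 3 (32139 to 34820), and miR-7 at 1879 in normal 3 (608 to 935), under both of its names, which share 1 sequence. MiR-1-3p stood at 346 in thin 2 (48.1 to 59.2), where the muscle list made up 0.170% (0.0845% to 0.0940%), and miR-199a-5p at 4338 in thin 4 (1436 to 2126).

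The real grouping called 9 small RNAs, and 2 of 100 splits of the 10 libraries, the real one included, called as many. That share was under the 0.05 set beforehand, but it does not exclude chance, since a grouping that mixed thin and normal camels called more. The highest other split called 10 and had the 3 deepest libraries on 1 side, as 17 of the 100 splits had, while splits with deep libraries on both sides, other than the real one, called at most 1. With the library depth class as a covariate 10 small RNAs were called, all 9 among them, which argues against depth class as the whole cause. Without the 3 deepest libraries 5 were called, 4 of them among the 9, with miR-21-5p at 1.002 (adjusted p = 0.173) and miR-486 at -1.14 (0.173). A difference that goes with thinness stays open, as an explanation that was not tested apart from the animals' other differences.

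The red blood cell list, lower in thin camels, was 1 of 2 called lists, a number that chance could give. Of 100 splits 68 called as many, and the highest other split called 7. That number does not bear on the red blood cell list itself. For single lists, 3 of 100 splits gave a p as small as that of the red blood cell list and 12 of 100 one as small as that of let-7. With miR-21 left out and library totals made equal, the median log2 fold change of the red blood cell list was -0.69 against -1.01. Equal totals alone moved the median of all small RNAs from -0.01 to 0.17, so this shift does not measure the part of miR-21. With miR-21-5p at only 5.35% of normal and 13.3% of thin libraries, the test could hardly have come out otherwise, so it decided nothing. Less red blood cell RNA in the plasma of thin camels, from fewer burst cells or fewer vesicles of these cells, would keep the ratios of these miRNAs: against miR-451a they changed by -0.49 for miR-486, -0.18 for miR-144-3p and -0.18 for miR-144-5p on the log2 scale, with a smallest exact p of 0.0556. That explanation cannot be told apart from separate changes of these miRNAs, because the spread of the miR-486 ratio allows, within 2 SE, a drop of up to 0.96.

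Normal 4 and normal 5 carried a signal that the comparisons did not address. Entries of the primate cluster made up 0.485% and 0.444% of these libraries and 0% to 0.0103% of the others. The 0.00296% of thin 4 argues against the greater depth of these libraries as the cause. For 9 miRNAs of the cluster, an entry without substitution was at 10 or more and at least 5 times the other libraries in both, so reads from a primate source may have entered these libraries. Entries without substitution held 41.5% and 42.4% of the cluster's counts in normal 4 and normal 5. Whether such reads also added to tested small RNAs was not tested. Entries with G9T (positions counted from 1 at the 5' end of the read) were as high in both libraries for 12 miRNAs, those of the cluster included. Outside the cluster they were so for 3 miRNAs, miR-142, miR-320b and miR-9993b, and no other of the 140 kinds of substitution had more than 1 such miRNA. The G9T entry of miR-142-5p was among the tested small RNAs, with a log2 fold change of -5.28 (limma adjusted p = 0.164). G9T was also the most frequent kind, listed for 41 miRNAs against at most 9 for any other, so it had more chances to be high there. Of the counts of entries that start at the same base, G9T made up 18.9% and 20.8% for miR-146a-5p and 17.7% and 21.3% for miR-142-5p. It made up 0.0148% and 0.0196% for miR-122-5p. Of 9 miRNAs with G at that position and 1527 or more normalized counts in both libraries, 6 had less than 10% of the highest share. This argues against a base error alike in all reads at 1 cycle, provided that such reads were listed alike. The G9T entry of miR-146a-5p averaged 282 ± 255 in normal and 221 ± 37.5 in thin camels (SD, n = 5 each). G9T was thus not confined to normal 4 and normal 5. MiR-320c, called higher in thin camels, was 7.1 and 13.1 in these libraries, where its G9T entry held more, 19.5 and 23.5, against at least 128 in thin camels, and no biological explanation was tested.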

How the results depend on the processing

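The fits without the 3 deepest libraries, without normal 4 and normal 5, with depth as a covariate, and the upper quartile and trimmed mean rescaling of the lists were chosen only after the results were seen. The 9 calls became 5 after upper quartile rescaling, 4 with limma without trend, 15 with no filter (6 shared, as 2581 were tested) and 14 with sample quality weights. They became 5 without the 3 deepest libraries and 3 without normal 4 and normal 5, where fewer samples remained. They ranged from 6 to 14 with each library left out, the 14 (6 higher and 8 lower) without thin 1. The 2 called lists stayed 2 after upper quartile rescaling with only 1 shared, as let-7 was lost (adjusted p = 0.122) and epithelial gained (median 0.75, adjusted p = 0.0372). They became 7 with no filter, 0 with an estimated correlation, 1 with fry, 6 with fry mixed, 4 with depth class as a covariate, 6 without the 3 deepest libraries, 6 without normal 4 and normal 5, and 0 without these with an estimated correlation. They ranged from 2 to 5 with each library left out, with 5 without normal 4 and 4 without normal 5. Except where fewer samples or other tested entries show it, the cause was not tested. The upper quartile factors could follow depth, since that quartile lay near the floor of 5 reads in the shallowest libraries. The median of the liver list ranged from -1.01 to 0.0799 with each library left out and was above 0 only without thin 4. MiR-127-3p and miR-381-3p turned to 0.59 and 0.71 without the 3 deepest libraries and to 0.57 and 0.59 without normal 4 and normal 5, and miR-26a-5p to 0.18 without the latter. MiR-381-3p and miR-26a-5p also changed sign with single libraries left out. Without thin 1 miR-200a-3p was 0.91 and miR-200b-3p 0.69, and without thin 2 miR-1-3p was 0.41. The 9 called small RNAs kept their direction in every alternative that tested them, with log2 fold changes of 1.002 to 1.33 for miR-21-5p, -1.57 to -1.14 for miR-486 (adjusted p of both up to 0.400), 3.07 to 4.51 for miR-335-5p and 2.60 to 3.83 for miR-320c. Equal library totals moved the median of all small RNAs to 0.17, with 8 calls. The weight difference, which only describes the grouping, stayed at -73.5 to -63.4 kg. No measure of composition and no arm ratio passed in any alternative, but few could have passed in families of this size, so this says nothing of their stability. With the replicate number as a replicate block there were 9 calls (8 shared) and 2 lists, but the numbers did not pair the camels: same-numbered deviations correlated at 0.18, 0.25, 0.03, 0.52 and -0.20, and not every library matched its own number best. Limma-voom on the estimated reads called 12, of which 9 were higher and 3 lower, with 8 shared, and miR-335-5p missed the threshold there (adjusted p = 0.0555). Other tests and thinning that need counts were not run. Depth limits small RNAs near 5 reads, about 5.27 normalized counts in the shallowest library and 0.825 in normal 4.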

Other observations

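All correlation tests in this part were chosen only after the results were seen. Some miRNAs varied together between camels of the same group, measured as deviations from group means over the 10 libraries, in a family of 6 relations chosen from shared cell type or shared transcripts. MiR-451a and miR-144-3p, which come from neighbouring hairpins of 1 red blood cell transcript, had a Pearson r of 0.972 (permutation p = 2.00e-05, adjusted 0.000120) and a Spearman rho of 0.988 (adjusted p = 0.000120), and r was 0.982 without the 2 farthest libraries. MiR-192-5p and miR-194-5p, which lie together in clusters expressed in liver and gut, had an r of 0.955 (permutation p = 9.00e-05, adjusted 0.000270) and a rho of 0.915 (adjusted p = 0.00138), with r = 0.939 without the 2 farthest. Within the 7 libraries outside the 3 deepest these values of r were 0.981 and 0.940. Both relations are consistent with a shared source, a shared red blood cell source or shared transcripts, that varies from camel to camel.

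MiR-451a and miR-486 had an r of 0.658 (permutation p = 0.0417, adjusted 0.0626) and a rho of 0.733 (adjusted p = 0.0295), with r = 0.564 without the 2 farthest libraries and 0.928 in the 7 others. MiR-200a-3p and miR-200b-3p had an r of 0.973 (adjusted permutation p = 0.00130) and a rho of 0.794 (adjusted p = 0.0194). The r fell to 0.616 without the 2 farthest libraries, thin 1 and normal 2, so its size rests in part on those libraries. It was 0.994 in the 7 libraries outside the 3 deepest, which still held both thin 1 and normal 2. MiR-122-5p had an r of 0.553 with miR-192-5p (adjusted permutation p = 0.119; rho = 0.527, adjusted 0.149) and of 0.444 with miR-194-5p (adjusted 0.194; rho = 0.358, adjusted 0.313), and neither relation passed.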
